A study of Mus musculus with 6 samples.

How the data were processed

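Total RNA from the ventral midbrain of male mice was extracted with Trizol, cleaned on Qiagen columns and labelled with biotin for Affymetrix arrays, per the labels' protocols. The authors deposited log2 expression values per probe set, 1 column per array, which had been background corrected, normalized between arrays and summarised with RMA, per the submitters' processing notes. The software version and annotation behind RMA were not given in the sources used here. The log2 scale itself was read from the deposited values, which run from 0.745 to 14.1. RMA gives every array nearly the same distribution, so a change that affected most genes alike would be removed, and it compresses differences of dim probe sets. The arrays still differed slightly in spread, with SDs of 2.36 to 2.38 on the knockout-labelled and 2.39 to 2.40 on the wild-type arrays. Fairly dim probe sets tended to read a little higher and bright ones a little lower on knockout-labelled replicates 1 and 2, but not on replicate 3. At a mean level of 4.81, the median deviations from the mean of all arrays were 0.052, 0.076 and -0.0024 on these 3. At a mean level of 7.59 they were -0.022, -0.052 and 0.0088. Over 10 bins of mean level with equal numbers of probe sets, the median log2 fold change ran from -0.044 to 0.077.

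Samples were grouped by the genotype in their labels into 3 Bach1 knockout and 3 wild-type arrays. Each array was used as deposited, and there were 0 further columns of sample values. Gene names came from a platform annotation and were updated through Entrez identifiers to a RefSeq gene table (assembly GRCm38.p6), which matched 23328 probe sets. That annotation gave 1 gene for 23521 probe sets, several for 1814 and none for 16010. Probe sets with several genes or none were not assigned to a single gene. No build is named in the files, so positions are not printed and the gene table served for names and for which genes neighbour each other. The design called for leaving out control rows by their names, and 0 rows carried such a name, so all 41345 probe sets entered the tests.

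Each probe set was tested with limma 3.58.1 (statmod 1.5.0) in R 4.3.3, with lmFit and eBayes without trend or robust variances, on all 6 arrays and without covariates. The fold change is knockout-labelled minus wild type on the log2 scale, intervals are at 95%, and a probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over all probe sets. The prior added 2.21 degrees of freedom. For gene lists, each gene was represented by its probe set with the highest mean over all arrays (22180 genes). Lists were tested with limma's camera with a preset correlation of 0.01 between genes, beside camera with an estimated correlation and fry, and adjusted over the 30 lists with Benjamini-Hochberg. Camera compares a list with the other genes, while fry asks whether a list's genes move, on balance, in 1 direction, and its mixed test whether they change in either. With an estimated correlation, camera also uses the few residual degrees of freedom of the 6 arrays. A list can then hardly pass over 30 lists, so a failure there says little about that list. The lists held 610 genes, of which 558 had a probe set of their own, and the others were not analysed here. Counts of genes near Bach1 used Fisher's exact test. A list's score on an array is the mean over its members of the log2 level minus the wild-type mean.

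The groups, tests, gene lists, named-gene rule and most alternatives were fixed before the data were examined. The rule names every Bach1 probe set and 12 index genes (antioxidant, iron and dopamine genes). It adds the 10 genes with the highest and the 10 with the lowest log2 fold change among called probe sets whose groups do not overlap, filled where fewer passed by the smallest unadjusted p among probe sets above the 40th percentile of mean level. From each list it takes up to 4 called members or, where none passed, up to 2 with the smallest unadjusted p, and it takes up to 5 called genes near Bach1. The unnamed probe sets that passed are given by their identifiers, and they were singled out after their values were seen, as was the probe set with the smallest p among lower ones. So was the neighbour of Bach1 in the count of genes near it.

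The lists were heme and iron handling, NRF2 antioxidant genes, CNC and small Maf factors, Parkinson disease genes, respiratory chain, mitochondrial biogenesis and dynamics, proteasome, autophagy and lysosome, unfolded protein and heat shock response, inflammatory cytokines, interferon response, synaptic and neurotrophin genes, circadian clock, immediate early genes and glucocorticoid response. Marker lists covered dopaminergic neurons, other neurons, microglia, astrocytes, oligodendrocytes and their precursors, vessels, ependyma and choroid plexus, meninges, blood, and the neighbouring regions cortex and hippocampus, hypothalamus and pituitary, thalamus, hindbrain and striatum.

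The tests were tested on simulated data before use. In 20 simulated data sets of 41345 probe sets with the spread of these arrays and 200 changed probe sets, limma recovered 4.03% of changes of 0.5 log2 units, 49.0% of changes of 1 unit and 81.5% of changes of 2 units, and 4.85% of its calls were false. The adjusted threshold is stricter when fewer probe sets change, and 3 passed in the real data. These rates are therefore not the sensitivity of the real comparison. Camera recovered a simulated shift of 0.3 log2 units in the heme and iron list in 100% of 50 data sets of independent genes. Alternatives left out dim probe sets (mean under the 40th percentile), repeated quantile normalization, subtracted array medians, used trended and robust variances, weighted arrays, added the replicate number as a block, left out each array in turn, took 1 value per gene, changed the threshold to an adjusted p under 0.1 or added a minimum log2 fold change of 0.5, and used windows of 5 and 20 Mb. Cyclic loess, a test of annotated probe sets alone and the heme list without Hmox1 were chosen after seeing the data.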

Results

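RNA from the ventral midbrain, the region that holds the dopamine neurons of the substantia nigra and ventral tegmental area, was measured on 6 Affymetrix mouse gene arrays. The tissue came from male mice 2 months of age. Of the arrays, 3 carried the label Bach1 knockout and 3 the label wild type. BACH1 is a transcriptional repressor that binds heme and competes with NRF2 for regulatory elements of antioxidant and iron genes. The values were log2 expression levels for 41345 probe sets, with array medians between 5.58 and 5.69. Pearson correlations between arrays, taken across probe sets, which are not independent replicates, ran from 0.984 to 0.989. No pair of arrays shared more than 0.256% identical values. The number of arrays limits the precision. The labels do not state that replicates were separate animals, so p-values measure the spread between these samples. The comparison addressed which transcripts of this region differed when Bach1 was knocked out.

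The Bach1 probe set (17326895) was read first, because it bears on the labels. Its level was 7.66 ± 0.058 (SD, n = 3) on the knockout-labelled arrays and 7.54 ± 0.068 (SD, n = 3) on the wild-type arrays. The log2 difference of 0.11 had a 95% interval of -0.085 to 0.31 and did not pass the test (limma, adjusted p = 0.74). The Bach1 signal was therefore not lower on the arrays labelled knockout, and the directions given here follow the labels. The structure of the knockout allele was not given in the sources used here, and a probe set that reads outside a deleted part checks nothing.

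Hmox1, which encodes the inducible heme oxygenase that degrades heme, was the named gene that rose. Its level (probe set 17502573) was 8.38 ± 0.15 (SD, n = 3) on the knockout-labelled arrays and 6.43 ± 0.098 (SD, n = 3) on the wild-type arrays, a 3.85-fold difference. The log2 fold change was 1.95 (SE 0.11, 95% interval 1.69 to 2.21; limma, adjusted p = 0.0181), and all 3 knockout-labelled arrays lay above all 3 wild-type arrays. A further 2 probe sets rose, and neither has a gene in the annotation used here. Probe set 17549062 was 5.09-fold higher, at 7.67 ± 0.13 against 5.33 ± 0.16, and probe set 17549150 was 5.61-fold higher, at 7.73 ± 0.13 against 5.24 ± 0.20 (SD, n = 3 for each; limma, adjusted p = 0.0181 for both). Both had close values on every array, so they may not be separate changes. These 3 were the whole set that passed an adjusted p of 0.05 among 41345 probe sets, and 0 passed in the lower direction, where the smallest adjusted p was 0.197. That value belongs to probe set 17494221, which the beta globin genes Hbb-b1, Hbb-b2 and Hbb-bs share in the annotation. It was at 4.37 against 5.29, with a log2 fold change of -0.93 and no overlap between the groups. Its mean lay below the 40th percentile of probe set means, and 2 further probe sets annotated to the same genes had log2 fold changes of 0.014 and -0.26 (adjusted p = 0.981 and 0.773). At an unadjusted p under 0.05 limma gave 3419 probe sets, 2054 higher and 1365 lower, against a nominal 2067, and the 9 other splits of the same arrays into 3 and 3 gave between 1469 and 3296. The knockout-labelled and wild-type values did not overlap for 14.3% of probe sets, against 10% by chance. With any single array left out, the test called 0 probe sets, while the log2 fold change of Hmox1 stayed between 1.88 and 2.03 in all alternatives. Without knockout-labelled replicates 1, 2 and 3 in turn the adjusted p of Hmox1 was 0.152, 0.134 and 0.189, and without wild-type replicates 1, 2 and 3 it was 0.191, 0.233 and 0.188.

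**Figure D1:**
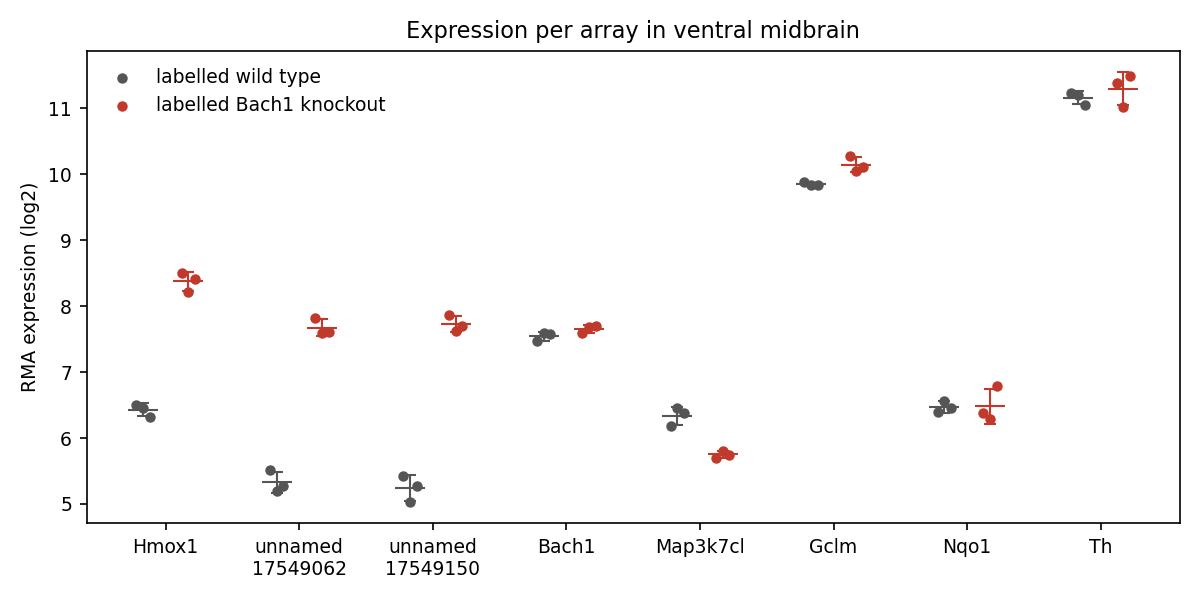
RMA expression (log2) of 8 probe sets on each array, with the group mean as a horizontal bar and the SD as whiskers, for the 3 arrays labelled wild type (grey) and the 3 labelled Bach1 knockout (red). Hmox1 and both unnamed probe sets separate the groups, with means of 8.38 against 6.43 for Hmox1, while Bach1 stands at 7.66 against 7.54.

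Among genes of heme and iron handling, Hmox1 was the member that passed. Of 20 measured members, 8 had a higher and 12 a lower mean on the knockout-labelled arrays, and 1 passed limma over all probe sets and also adjusted over the list alone. Fth1, the ferritin heavy chain, had a log2 fold change of 0.13 (95% interval -0.052 to 0.32, adjusted p = 0.682), and its 3 knockout-labelled values lay above the wild-type values. Alas1 of the same list separated in the lower direction (log2 fold change -0.052, limma, adjusted p = 0.875). Over all probe sets, 14.3% separated in either direction. Slc40a1, the iron exporter ferroportin, had a log2 fold change of -0.10 (95% interval -0.38 to 0.18, adjusted p = 0.838). As a group the list did not pass (camera, adjusted p = 0.812), with a median of -0.010 and a mean of 0.083 that differ in sign. Ftl1 had no probe set of its own and was not analysed here.

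Among 34 measured NRF2 antioxidant genes, 20 had a higher and 14 a lower mean on the knockout-labelled arrays, and 0 passed over all probe sets or adjusted over the list alone, with 3 at an unadjusted p under 0.05 (limma). Gclm, the modifier subunit of the enzyme that starts glutathione synthesis, was at 10.14 ± 0.12 against 9.85 ± 0.024 (SD, n = 3), a log2 fold change of 0.30 with a 95% interval of 0.079 to 0.51 that did not pass (limma, adjusted p = 0.538). Gsta3, a glutathione transferase, had a log2 fold change of -0.53 (adjusted p = 0.543). Srxn1, which encodes sulfiredoxin, had a log2 fold change of 0.10 (95% interval -0.15 to 0.36). The quinone reductase Nqo1, the catalytic ligase subunit Gclc and the thioredoxin reductase Txnrd1 had log2 fold changes of 0.011, -0.0086 and -0.0017, with 95% intervals of -0.35 to 0.37, -0.19 to 0.18 and -0.23 to 0.23, and each of these changed sign under some rescaling of the arrays. Slc7a11, the cystine and glutamate exchanger, had a log2 fold change of 0.15 with a wide 95% interval of -0.54 to 0.83, and its value was -0.14 without wild-type replicate 1. The list as a group did not pass (camera, adjusted p = 0.893). Of 10 CNC and small Maf transcription factors, 5 had a higher and 5 a lower mean and 0 reached an unadjusted p under 0.05; Maff had a log2 fold change of 0.18 (adjusted p = 0.768), and the list did not pass (camera, adjusted p = 0.809).

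**Figure D2:**
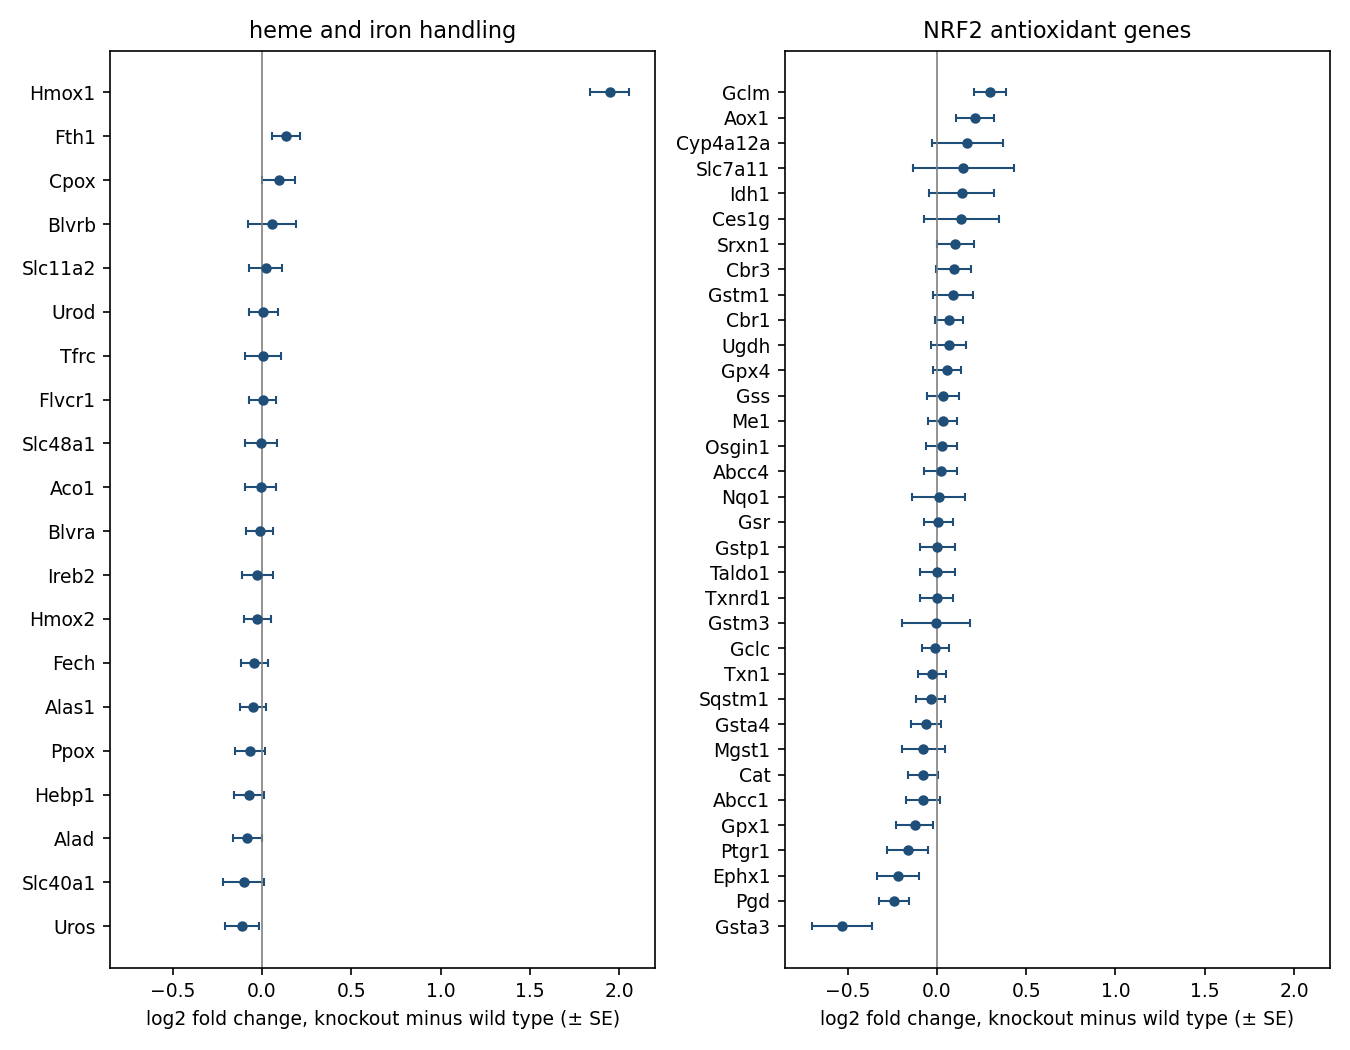
Log2 fold change (knockout-labelled minus wild-type arrays, n = 3 each, bars show the SE) of each measured gene of heme and iron handling (left) and of the NRF2 antioxidant list (right), 1 row per gene. Hmox1 stands at 1.95, and the highest NRF2 list member, Gclm, at 0.30.

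As a group, dopaminergic neuron markers had slightly higher means on the knockout-labelled arrays, without passing the test. Of 26 measured genes 21 were higher and 5 lower, with a median log2 fold change of 0.14 (camera, adjusted p = 0.0903, and adjusted p = 0.941 with an estimated correlation). Th, the rate-limiting enzyme of dopamine synthesis, had a log2 fold change of 0.14 (95% interval -0.21 to 0.48), and the dopamine transporter Slc6a3 one of 0.15 (95% interval -0.16 to 0.46). Aldh1a1 was at 0.26 (adjusted p = 0.564) and the calcium-binding protein gene Calb1 at -0.28 (adjusted p = 0.598). Limma called 0 of the 26 genes over all probe sets or adjusted over the list alone, and 2 reached an unadjusted p under 0.05. The list's score was 0.12 and 0.22 on knockout-labelled replicates 1 and 3 and -0.098 on replicate 2, while the wild-type scores ran from -0.087 to 0.047. Knockout-labelled replicate 2 also had the highest cortex and hippocampus score of all arrays (0.362) and the lowest oligodendrocyte score (-0.203). A link between these scores was not tested. The list passed without knockout-labelled replicate 2 (camera, adjusted p = 3.56e-05), without wild-type replicate 2 (adjusted p = 0.0346), without dim probe sets (adjusted p = 0.0197) and after renewed quantile normalization (adjusted p = 0.0259).

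Gene groups linked to Parkinson disease, mitochondria and protein turnover did not pass as lists, and limma called 0 of their members, with 0 at an unadjusted p under 0.05 in each. Parkinson disease genes had 5 higher and 8 lower among 13 measured (camera, adjusted p = 0.744), with log2 fold changes of -0.15 for Uchl1 and -0.16 for the monoamine oxidase Maob. The mitochondrial respiratory chain had 26 higher and 16 lower among 42 (adjusted p = 0.744), with Cox4i1 at 0.16 and Sdhc at -0.15. Mitochondrial biogenesis and dynamics had 12 higher and 8 lower among 20 (adjusted p = 0.809), with Tfb1m at -0.14 and Esrra at 0.13. Proteasome subunits had 18 higher and 12 lower among 30 (adjusted p = 0.809), with Psma6 at 0.12 and Psmb4 at 0.11. Autophagy and lysosome genes had 8 higher and 15 lower among 23 (adjusted p = 0.812), with the cathepsins Ctss at 0.13 and Ctsl at -0.12. The unfolded protein and heat shock list had 11 higher and 14 lower among 25 (adjusted p = 0.944), with Sdf2l1 at 0.17 and Hspa1a at -0.45. Synaptic vesicle and neurotrophin genes had 7 higher and 14 lower among 21 (adjusted p = 0.741), with Vegfa at -0.23 and Stx1a at -0.18.

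In 5 of the 30 gene lists fixed before the data were examined, members shifted together past the threshold with camera at its preset correlation of 0.01, 2 toward higher and 3 toward lower values on the knockout-labelled arrays. With an estimated correlation 0 lists passed, and fry called 0 in its directional test, with smallest adjusted p-values of 0.795 and 0.13. The estimated form uses few degrees of freedom, so a list could hardly pass it. Its adjusted p of 0.941 equals the largest unadjusted p of the 30 lists and does not tell lists apart. Glucocorticoid response (camera, estimated correlation, unadjusted p = 0.115) and astrocyte markers (unadjusted p = 0.865) both had it. In fry's mixed test, which asks for change in either direction, 1 list passed, heme and iron handling (adjusted p = 0.000866), and it did not pass without Hmox1 (adjusted p = 0.694). Glucocorticoid response genes were the first of the higher lists, with 13 of 16 members higher and a median log2 fold change of 0.15 (camera, adjusted p = 0.00652, and adjusted p = 0.941 with an estimated correlation). The transcription factor gene Zbtb16 had a log2 fold change of 0.66 (adjusted p = 0.54) and Pdk4, a kinase that restrains pyruvate oxidation, one of 0.25 (adjusted p = 0.569). Other members, singled out after the values were seen, were nearly flat. Fkbp5 was at 0.019, Errfi1 at 0.0066, Mt2 at 0.020, Mt1 at -0.0037 and Ddit4 at -0.0040. The list's score on all 3 knockout-labelled arrays, 0.28, 0.12 and 0.13, lay above the highest wild-type score of 0.034, and without knockout-labelled replicate 1 the list's adjusted p was 0.0975. With 3 against 3 arrays, 10% of scores separate by chance. The scores of the heme, hindbrain and interferon lists also separated, and the heme score includes Hmox1. Serotonergic and hindbrain markers were higher in 13 of 17 members, with a median of 0.11 (camera, adjusted p = 0.0108, and adjusted p = 0.795 with an estimated correlation). The serotonin transporter Slc6a4 was at 5.18 ± 0.25 against 4.60 ± 0.087 (SD, n = 3), and Tph2, the enzyme of serotonin synthesis in neurons, at 5.07 ± 0.20 against 4.74 ± 0.030. These levels are low, and 7 of the 17 genes lay above the 40th percentile of probe set means (5.07). Probe sets of like brightness (mean level 4.81) had a median log2 fold change of 0.077, and the list did not pass without dim probe sets (adjusted p = 0.539), after renewed quantile normalization (adjusted p = 0.184) or without knockout-labelled replicate 3 (adjusted p = 0.0743).

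Hypothalamus and pituitary markers had the largest median shift of the 30 lists. Of 16 measured genes 14 were lower on the knockout-labelled arrays, with a median log2 fold change of -0.54 (camera, adjusted p = 0.00652, and adjusted p = 0.941 with an estimated correlation). The releasing hormone gene Trh was at 7.38 ± 0.77 against 8.97 ± 0.94 (SD, n = 3), 3.0-fold lower, and did not pass (limma, adjusted p = 0.569). The pituitary hormone gene Prl was at 3.95 ± 0.31 against 4.38 ± 0.16. The score of this list overlapped between the groups, from -1.10 to -0.38 on the knockout-labelled and from -0.46 to 0.51 on the wild-type arrays, and without knockout-labelled replicate 3 the list's adjusted p was 0.19. The lowest wild-type score was on replicate 1, which stood apart from wild-type replicates 2 and 3 in other region lists too. Striatum scores were -0.296 against 0.145 and 0.151, and thalamus scores 0.296 against -0.167 and -0.129. Interferon response genes were lower in 17 of 20 members, with a median of -0.13 (camera, adjusted p = 0.0107, and adjusted p = 0.941 with an estimated correlation). Oasl2 had a log2 fold change of -0.35 (adjusted p = 0.565) and Ifit1 one of -0.24 (adjusted p = 0.588), both genes being induced by interferon. All 3 knockout-labelled scores lay below the lowest wild-type score of -0.032, a separation with a chance share of 10%. Replicates 1 and 3 lay close to it, at -0.060 and -0.054. Replicate 2 was the lowest at -0.29, and without that replicate the adjusted p was 0.274. Endothelial and mural cell markers were lower in 17 of 20 members, with a median of -0.15 (camera, adjusted p = 0.0109, and adjusted p = 0.941 with an estimated correlation). The pericyte receptor gene Pdgfrb had a log2 fold change of -0.30 (adjusted p = 0.597) and the channel subunit gene Abcc9 one of -0.24 (adjusted p = 0.612). The scores overlapped, with -0.088 on wild-type replicate 1 below -0.052 and -0.084 on knockout-labelled replicates 1 and 3. Meningeal fibroblast markers were lowest on the same arrays, with scores of -0.70 on knockout-labelled replicate 2 and -0.67 on wild-type replicate 1. Knockout-labelled replicate 2 had the lowest endothelial score, at -0.29, and the adjusted p was 0.264 without it, 0.119 without wild-type replicate 2 and 0.0592 after renewed quantile normalization. Limma called 0 members of these 5 lists over all probe sets or adjusted over each list alone, with between 1 and 3 members per list at an unadjusted p under 0.05.

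**Figure D3:**
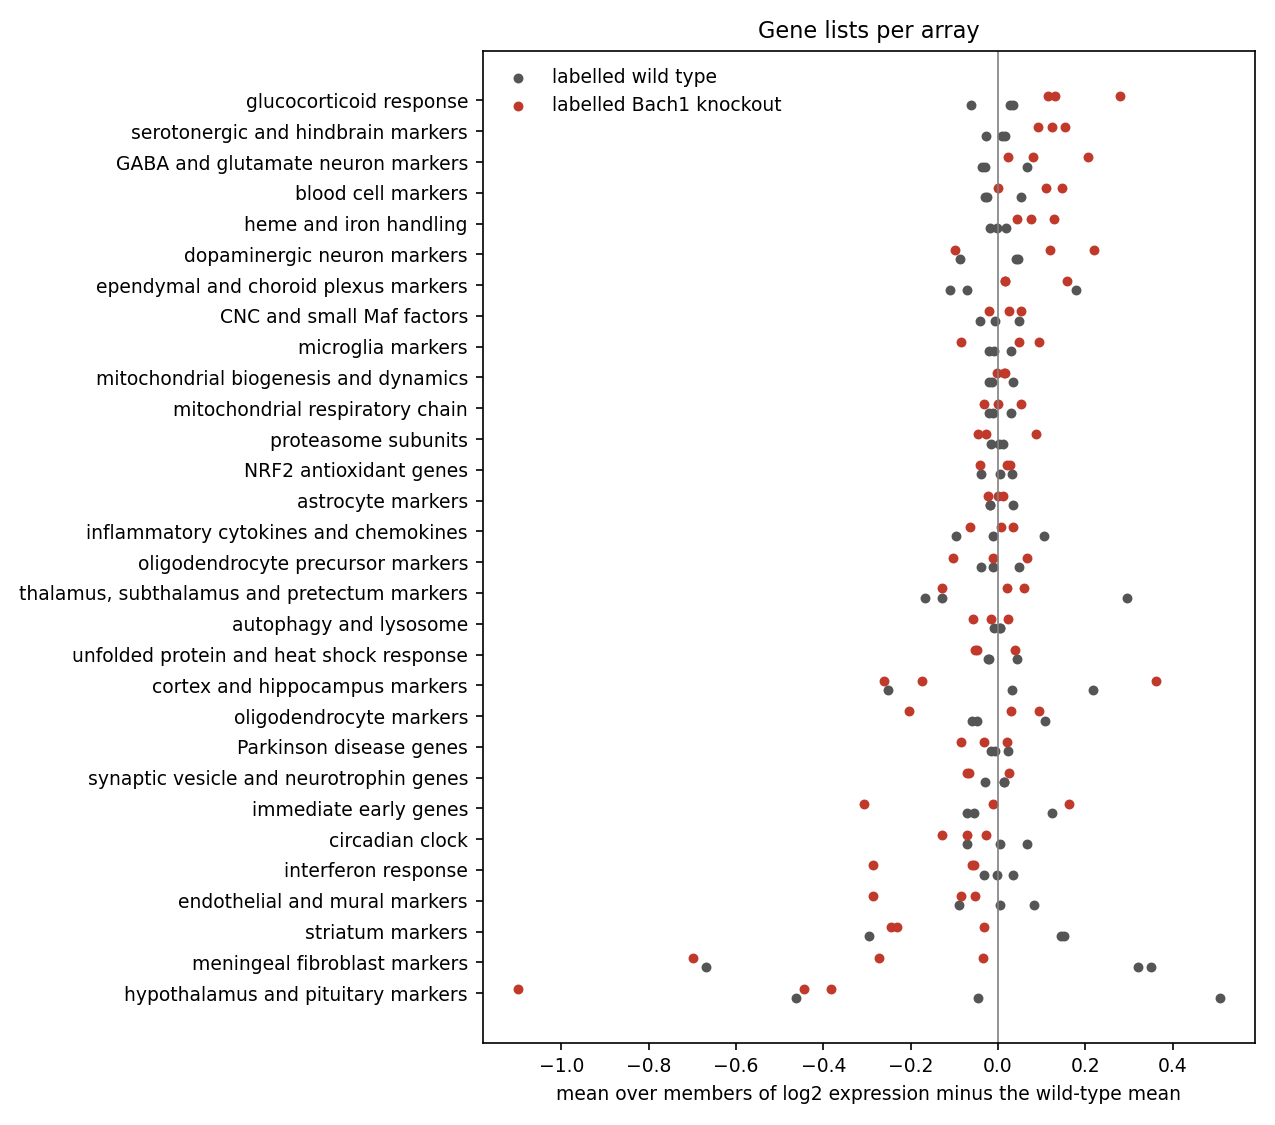
Score of each of the 30 gene lists on each array, as the mean over members of log2 expression minus the wild-type mean, for the 3 arrays labelled wild type (grey) and the 3 labelled Bach1 knockout (red), 1 row per list. The hypothalamus and pituitary list spans -1.10 to 0.51 over the 6 arrays. Scores of the glucocorticoid, heme, hindbrain and interferon lists do not overlap between the groups. By chance, 10% of scores would not overlap with 3 against 3 arrays.

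Other cell type and region markers did not pass. Meningeal fibroblast markers were lower in 12 of 14 members (camera, adjusted p = 0.105), with Ptgds at a log2 fold change of -0.38 and Slc6a13 at -0.73, and their scores of -0.67 on wild-type replicate 1 and -0.70 on knockout-labelled replicate 2 stood apart from 0.35 and 0.32 on the other wild-type arrays. This list passed without wild-type replicate 1 (adjusted p = 1.52e-06) and without knockout-labelled replicate 1 (adjusted p = 0.0139) at the preset correlation, and over all arrays it had an adjusted p = 0.941 with an estimated correlation. Striatum markers were lower in 10 of 11 members (adjusted p = 0.186), with Tac1 at -0.66 and Pdyn at -0.40, and passed without wild-type replicate 1 (adjusted p = 0.000291) and without knockout-labelled replicate 1 (adjusted p = 0.042) at the preset correlation. For striatum, cortex, circadian clock and immediate early genes, too, the adjusted p = 0.941 with an estimated correlation over all arrays. GABA and glutamate neuron markers were higher in 11 of 16 (adjusted p = 0.265), with Pou4f1 at 0.59 and Six3 at -0.18. Cortex and hippocampus markers were higher in 8 and lower in 6 of 14 (adjusted p = 0.696), with a median of 0.0063 that became -0.27 without knockout-labelled replicate 2, where the list passed as lower (adjusted p = 0.0138). In that list Wfs1 was at 9.39 ± 0.041 against 9.80 ± 0.10 (SD, n = 3), which passed adjusted over the list alone but not over all probe sets (limma, adjusted p = 0.512), and Rasgrf2 had a log2 fold change of -0.28. Thalamus, subthalamus and pretectum markers were higher in 6 and lower in 9 of 15 (adjusted p = 0.809), with Barhl2 at -0.29. Microglia markers were higher in 13 and lower in 4 of 17 (adjusted p = 0.744), with Siglech at -0.34 and Cx3cr1 at 0.16. Astrocyte markers were split 9 and 9 among 18 (adjusted p = 0.929), with Gjb6 at -0.19 and Cldn10 at 0.12. Oligodendrocyte markers were higher in 6 and lower in 10 of 16 (adjusted p = 0.812), with Opalin at -0.24 and Ugt8a at 0.17, and precursor markers higher in 7 and lower in 5 of 12 (adjusted p = 0.929), with Tmem100 at -0.24 and Matn4 at 0.13. Ependymal and choroid plexus markers were higher in 9 and lower in 5 of 14 (adjusted p = 0.744), with Slc4a5 at 0.40 and Tmem212 at -0.46. Of the blood cell markers 6 had a probe set of their own, 3 higher and 3 lower (adjusted p = 0.741), with S100a9 at 0.36 and Ngp at 0.34, and the adult globins had no probe set of their own and were not counted in this list.

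Circadian clock genes had lower means in 13 of 16 members, with Bhlhe41 and Dbp both at -0.16 (camera, adjusted p = 0.105). That list passed without wild-type replicate 3 (adjusted p = 0.0305) and with trended, robust variances (adjusted p = 0.0396). Immediate early genes were higher in 9 and lower in 11 of 20 (adjusted p = 0.744, and 0.0386 without knockout-labelled replicate 2), with Btg2 at -0.57 and Dusp1 at -0.46. Inflammatory cytokines and chemokines were higher in 10 and lower in 12 of 22 (adjusted p = 0.936), with Il1a at 0.29 and Tgfb1 at -0.23. Over these and the other lists, the members that passed limma were Hmox1 over all probe sets and Wfs1 within its list. In the unfolded protein, inflammatory and astrocyte lists the median and mean were below 0 while camera's direction was up, and in the oligodendrocyte precursor and cortex lists the median was above 0 while the mean and camera's direction were down.

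Because so few genes passed, the remaining named genes are those with the smallest unadjusted p in each direction, and none of them passed (limma, adjusted p = 0.512 for each). Among the higher ones, the kinase gene Aurkc had a log2 fold change of 0.79, Olfr1077-ps1 of 0.65, Rhox6 of 0.64, Gal3st2 of 0.59, Trim80 of 0.56, the transcription factor gene Nfic of 0.55, the claudin gene Cldn23 of 0.54, Treml4 of 0.49 and the keratin gene Krt81 of 0.40. Among the lower ones, the defensin gene Defb1 was at -0.85, Trim30d at -0.66, Btn2a2 at -0.59, Map3k7cl at -0.58, Zfp964 at -0.48, the transcription factor gene Tox at -0.48, Nanp at -0.45, 2310075C17Rik at -0.41, Wfs1 at -0.41 and Naprt at -0.39. The brighter ones were Nfic (9.46 against 8.91), Wfs1 and Tox (7.22 against 7.70), and the group means of the others lay between 4.82 for Cldn23 and 6.90 for Gal3st2.

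Genes close to Bach1 on its chromosome, where a bred knockout allele can carry flanking donor DNA, were counted separately. Of 142 genes within 10 Mb of Bach1, 0 were called by limma, and with 1 gene called among the 21851 elsewhere this count decides nothing. At an unadjusted p under 0.05 the counts were 8 of 142 (5.63%) and 1413 of 21851 (6.47%; two-sided Fisher's exact test, p = 0.864). Map3k7cl, the neighbour of Bach1 among genes with a probe set of their own, had the smallest p of this stretch. It was at 5.75 ± 0.050 against 6.34 ± 0.14 (SD, n = 3), 1.5-fold lower on the knockout-labelled arrays, with all 3 values below all 3 wild-type values, and did not pass (limma, adjusted p = 0.512).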

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

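Of 1751 values recomputed under alternatives, 1691 kept their side of the threshold or stayed within 1.5 times the count, 23 no longer passed, 15 newly passed, 22 counts moved and 0 called results reversed. Among the named genes Hmox1 alone passed, so most of these values lay far from the threshold and had little room to change. The total therefore says little about the results that did pass. Of 85 named genes, 4 that did not pass in any setting changed sign under some alternative (Gclc, Nqo1, Slc7a11 and Txnrd1). The median or camera direction also changed sign under some alternative in 19 of the 30 lists, in up to 10 alternatives (oligodendrocyte precursors), and none of these 19 passed with the settings of the report. The count of called probe sets, 3 and all higher, was 1 with annotated probe sets alone (chosen after seeing the data), with 1 probe set per gene and with the mean of a gene's probe sets, where the unnamed probe sets are not tested. It was 0 when any 1 array was left out (range 0 to 0), where fewer samples enter. With the replicate block, the count was 0 and Hmox1 had a log2 fold change of 1.95 with an adjusted p of 0.544. The labels do not say whether replicate numbers pair the arrays. Deviations of same-numbered arrays from their group means correlated at 0.0864, -0.0326 and 0.0395, which shows no sign of pairing. With 3 arrays per group these values cannot exclude it. The block uses up residual degrees of freedom. Over its 14 alternatives Hmox1 had a log2 fold change of 1.88 to 2.03 and an adjusted p of 0.00198 to 0.544, and it was called in 7. The Bach1 probe set and the count of genes near Bach1 kept their side throughout. Gene lists called went from 5 to 0 with an estimated correlation and ranged from 3 to 7 with 1 array left out. The estimate was 0.34 for hypothalamus and pituitary, 0.245 for endothelial, 0.241 for interferon and 0.182 for glucocorticoid genes. These lie above the preset 0.01, so the preset p-values of these lists are likely too small. For hindbrain markers the estimate was -0.0278, so a higher correlation does not account for the loss of that call. The estimated form also uses fewer degrees of freedom, which does account for it (camera, unadjusted p = 0.0265 against 0.00144 at the preset). This applies to every list, so the fall from 5 to 0 cannot be put down to correlation alone. Dopaminergic markers (adjusted p = 0.0903) passed without dim probe sets (0.0197), after quantile normalization (0.0259), with trended, robust variances (0.0204), with array weights (0.0365) and after cyclic loess (0.0198, chosen after seeing the data), and ranged from 3.56e-05 to 0.837 with 1 array left out, with alternatives from 0.0197 to 0.941 otherwise. The cause of these changes was not tested. The passes of this list used the preset correlation, while its estimate was 0.411, so those p-values are likely too small as well. Endothelial markers also missed the threshold after cyclic loess (0.0546), as did hindbrain markers (0.184). No background level was measured, so what signal over background limits is unknown here.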

Other observations

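The tests of exchanged labels, lost Bach1 RNA, flanking DNA and dissection were chosen after the results were seen. Renewed quantile normalization had been chosen before the data were examined, and its use as a test of array scaling afterwards.

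With 6 arrays there are 10 splits into 3 and 3, too few for a share under 0.05. The real split called 3 probe sets, the highest other count was 1, and 1 of the 10 splits, the real split, reached 3. The unnamed probe sets among these may not be separate changes. The real split called 5 gene lists, the highest other count was 10, on the split that joins knockout-labelled replicates 1 and 3 with wild-type replicate 1, and 5 of the 10 splits reached 5.

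The Bach1 signal did not fall on the knockout-labelled arrays. If Hmox1 follows the Bach1 genotype, an exchange of some arrays between the groups, or a single wrong label, would put an array into the Hmox1 range of the other group. The lowest knockout-labelled Hmox1 level exceeded the highest wild-type level by 1.71 log2 units, against a widest range within a group of 0.286, which argues against such a partial exchange. A complete exchange of both groups' labels would turn the sign of that gap. Given that BACH1 is known to repress Hmox1, the lower 95% limit of 1.69 for the Hmox1 log2 fold change argues against it, and the direction of Hmox1 used in this way is then no separate evidence of repression. A loss of the RNA that the probe set reads is also argued against, since the lower 95% limit of the Bach1 log2 fold change was -0.0849. A candidate explanation that stays open is an allele that leaves this part of the Bach1 RNA in place, which could not be tested without the structure of the allele or the positions of the probes.

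Map3k7cl, next to Bach1, had a log2 fold change of -0.58 that did not pass over all probe sets. Donor DNA around the Bach1 allele may differ from the wild-type strain over a broad stretch. The share of genes within 10 Mb at an unadjusted p under 0.05 was 5.63% (exact 95% interval 2.46% to 10.8%) against 6.47% elsewhere, so an excess is neither shown nor excluded. An effect of the altered allele on its neighbour, a difference confined to Map3k7cl's own sequence, and chance among 142 genes stay open and were not tested.

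Hypothalamus and pituitary markers were lower on the knockout-labelled arrays at the preset correlation of camera. Scaling of the arrays as the whole cause is argued against, because the list still passed after renewed quantile normalization (adjusted p = 0.000567, with alternatives from 0.000567 to 0.941). The position of the dissection, which borders the hypothalamus, is a candidate explanation. With the group means removed, list members varied together over the arrays with a mean correlation of 0.34, above 99.99% of 10000 random lists matched on level, and the wild-type arrays alone spanned -0.46 to 0.51 in score. Lists that mark no region also varied together, at 0.241 for interferon response, 0.182 for glucocorticoid response and 0.245 for endothelial and mural markers (percentiles of 100, 98.1 and 99.7), so this test is not particular to dissection, and other variation between the samples stays open. The brightest members were Sst (11.2 on the wild-type arrays), Pmch (11) and Hcrt (10), with log2 fold changes of -0.23, -1.36 and -1.14 that did not pass (limma, adjusted p = 0.818, 0.699 and 0.727). The SD of Pmch and Hcrt was 1.69 and 1.65 on the knockout-labelled arrays, against 0.50 and 0.33 on the wild-type arrays, and without knockout-labelled replicate 3 the list did not pass (adjusted p = 0.19). Of the list, 13 of the 16 members lay above the level of dim probe sets and 1 is also in another list. An effect of the genotype on these neuropeptide genes stays open and was not tested apart from the dissection.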
